A study of Oryza sativa with 9 samples.

How the data were processed

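RNA was measured in roots of 7-day-old rice plants (Oryza sativa, cultivar Dongjin) grown in soil under 10 h of light and 14 h of dark. The labels put 9 libraries in 3 groups of 3: wild type (WT), the line dgk1, which the labels give as a knockout of a diacylglycerol kinase, and OE2, given as an overexpression line. The design text calls the 3 libraries of a line biological repetitions. How many plants went into each library is not given in the sources used here.

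The deposited values are in FPKM, fragments per kilobase of gene model scaled to depth; the unit was read from the values and the length column, since no header or label names it. CASAVA 1.8 and HISAT2 are named in the submitters' processing notes. The counting tool, the genome build and the annotation are not given in the sources used here, so coordinates are given as the files list them, and genes keep the files' identifiers and descriptions. The per-model length, in bases, is per the file headers. Each file lists 105692 gene models: 37830 with an OS identifier, here called annotated, 13958 that carry a running number in place of one, here called numbered models, and 53904 noncoding models. A numbered model is written with its number, for example model 25546. Whether counting used strand is not given in the sources used here, so antisense or overlapping models cannot be told apart.

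Value times length was a whole multiple of 1 step in each library for 100% of values, within a tolerance of 0.01. This gave back whole fragments and the depth, 8908397 to 12459460 fragments per library. The depth each value was divided by equalled a median-of-ratios size factor times the geometric mean of the totals, so the deposited values already carry a scaling between libraries. An FPKM value of 0 is reported as listed at 0. Of the annotated models that share their span with a numbered model, 76.0% were listed at 0 in all libraries, against 31.9% of the others, and 2 of 4 elongation factor 1-alpha models were at 0, so an annotated model at 0 can be an unfilled estimate.

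The tests planned for counts were not used, because the files hold FPKM. As fixed for that case before the data were examined, limma 3.58.1 (R 4.3.3 with statmod 1.5.0) was run with an intensity trend and robust variance on log2(FPKM + 1). Models with at least 1 FPKM in at least 3 of the 9 libraries were kept: 22383, of which 13945 were annotated, 5769 numbered and 2669 noncoding. All 9 libraries entered 1 fit with the group as its only term. Calls were made two-sided at a Benjamini-Hochberg adjusted p of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Means are given as ± SD over n = 3 libraries, and log2 fold changes as ± SE.

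The genes named in the text were chosen by a rule fixed before the data were examined: the diacylglycerol kinase models; the 8 largest rises and 8 largest falls per comparison (4 and 4 between both lines) among called models with at least 5 FPKM in the higher group, no overlap between replicates and a description that names a function; and up to 4 called members of each called gene list. OS04G0634700 was taken as the study's target from background knowledge of its identity. Genes named beyond the rule are said to have been chosen after their values were seen. Gene lists were matched on the files' descriptions: 36 were fixed beforehand, 35 had at least 5 tested members, and the list of circadian clock genes had 1. They were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 35 lists of a comparison, and again with an estimated correlation.

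The test was checked on 5 simulated sets per comparison, with fragments drawn from the means and depths of the libraries and known changes put in. Every model was given the same spread between replicates (dispersion 0.0175), and only models with a mean of at least 2 FPKM were changed. Spread that differs between genes or libraries was thus not simulated, and the shares below hold for that setting only. The share of 4-fold changes recovered was 91.5% for dgk1 against WT, 89.7% for OE2 against WT and 92.1% for OE2 against dgk1. For 2-fold changes it was 47.5%, 49.3% and 51.6%, and for 1.5-fold changes 6.27%, 4.78% and 5.07%. False calls made up 8.54% (45 of 527), 11.7% (63 of 540) and 10.8% (60 of 554) of all calls, above the 5% aimed at, and 44, 61 and 56 of them were noncoding models. After a first run of this check, the dispersion was re-estimated over the 3 groups in place of 1 group, which lowered the recovery, and the simulation was extended to 5 sets. Replicates of a group differed by more than sampling noise in all 9 pairs, with a chi-square per degree of freedom of 5.13 to 19.2, so all 9 libraries were counted.

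Alternatives tried were no filter and a filter of 5 FPKM, a pseudocount of 0.1, a fold threshold, the 6 libraries of a comparison alone, the replicate number as a block, and each library left out in turn. Added after seeing the data were a rescaling to total fragments, quantile normalization, limma's voom on the recovered fragments, annotated models alone, models without the noncoding ones, and models outside chromosomes 6, 11 and 12. The calls of single named genes were not followed in the fits of annotated models alone, without noncoding models or outside those chromosomes. A genome sequence and a list of locus tags were not used here.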

Results

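Root RNA of 3 rice lines was compared: the wild type, a line labelled as a knockout of diacylglycerol kinase 1 (dgk1) and a line labelled as its overexpressor (OE2). Diacylglycerol kinases phosphorylate diacylglycerol to phosphatidic acid, and both lipids act as signals in plants. The study asks how this kinase and its lipids bear on root architecture. Each line had 3 libraries, with 8908397, 10574056 and 12459460 fragments for WT, 12346054, 10536887 and 12000414 for dgk1 and 9846049, 9825343 and 9786426 for OE2. Along the first principal component, with 38.5% of the variance, the OE2 libraries lay between 60.3 and 67.1 and the other 6 between -39.8 and -25.2. Along the third, with 11.9%, WT replicate 1 stood apart at 53.8 and OE2 replicate 2 at 32.8, against -12.2 and -12.9 for the other OE2 libraries.

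The targeted gene, OS04G0634700 on chromosome 4 (32286661 to 32291433, plus strand), is described in the files as a diacylglycerol kinase and was listed at 0 FPKM in all 9 libraries. Fragments at this locus were listed under model 25546, a numbered model with the same span and with diacylglycerol kinase catalytic and accessory domains. Its values were 0.896, 0.738 and 0.487 FPKM in the libraries labelled WT, 7.24, 5.60 and 9.16 FPKM in those labelled dgk1, and 0.521, 0.625 and 0.571 FPKM in those labelled OE2. In fragments, the sums were 66, 791 and 48. Model 25546 rose in the libraries labelled dgk1, from 0.707 ± 0.206 to 7.33 ± 1.79 FPKM (SD, n = 3; log2 fold change 2.27 ± 0.18, limma adjusted p = 0.000687). It was not called in those labelled OE2 (log2 fold change -0.11, adjusted p = 0.779), where the ratio of fragments to WT, scaled for depth, was 0.848 with a 95% interval for counting error of 0.572 to 1.25. The ratio for dgk1 was 10.97 (8.53 to 14.3). The values listed under model 25546 thus go against both labels, while the level of OS04G0634700 itself cannot be read from values at 0. Their lengths differ, at 1964 bases for OS04G0634700 and 2946 for model 25546. The groups are named in what follows only as the libraries are labelled. Whether the fragments lie in the coding part or near an insertion cannot be read from values per gene model.

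**Figure D1:**
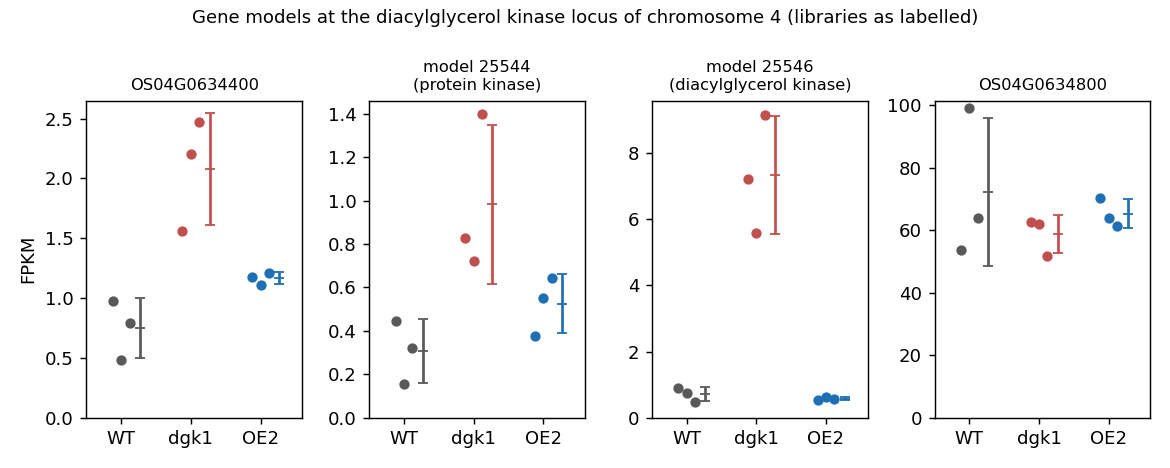
FPKM of 4 gene models at the diacylglycerol kinase locus of chromosome 4 in each library (points), with mean and SD (bars, n = 3), grouped by label. Model 25546, with the span of the targeted gene, lay at 5.60 to 9.16 FPKM in the libraries labelled dgk1 and below 1 FPKM in the other 6.

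Of 17 models described as diacylglycerol kinases, 9 were listed at 0 in every library and 5 were tested. Besides model 25546, model 11163 on chromosome 12 rose in the libraries labelled OE2, from 29.6 ± 5.39 to 45.1 ± 2.99 FPKM (log2 fold change 0.61 ± 0.14, limma adjusted p = 0.0368). This call was lost in 9 alternatives, 5 of them leaving out a single library (limma adjusted p over all alternatives up to 0.116). On chromosome 12, 13.8% of tested models were called in OE2 against WT, so a local difference cannot be told apart. Model 34608 on chromosome 7 lay at 2.42 ± 0.582, 2.21 ± 0.471 and 3.69 ± 0.294 FPKM in WT, dgk1 and OE2, and model 15899 on chromosome 2 at 3.91 ± 0.320, 3.22 ± 0.262 and 3.89 ± 0.606 FPKM. OS01G0783200 lay at 1.32 ± 0.525, 1.75 ± 0.0807 and 1.52 ± 0.510 FPKM. None of these 3 passed the test in any comparison.

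OS02G0252400, a Dof zinc finger protein of a family of plant transcription factors, was listed at 0 in all WT libraries and at 7.90, 8.43 and 10.5 FPKM in the libraries labelled dgk1 (chromosome 2, 8590318 to 8593735; log2 fold change 3.31 ± 0.20, limma adjusted p = 9.55e-05). Model 31587, with a Myb/SANT-like DNA-binding domain, rose from 0.206 ± 0.137 to 9.50 ± 1.77 FPKM, and model 36678, with the FAR1 DNA-binding domain known from light signalling factors, from 8.12 ± 1.596 to 23.6 ± 3.43. Model 36605 rose from 1.24 ± 0.802 to 13.7 ± 3.95 FPKM (log2 fold change 2.75 ± 0.31, limma adjusted p = 0.00623). Its domain is listed as GDSL/SGNH-like acyl-esterase, a family found in Pmr5 and Cas1p, and its activity cannot be read from that name. Laccase-8 (OS01G0850800), of the enzymes that oxidize lignin precursors, rose from 1.299 ± 0.620 to 5.75 ± 0.874, model 13790, a leucine-rich repeat kinase, from 3.80 ± 0.698 to 9.97 ± 0.363, and the purple acid phosphatase OS11G0151700 from 5.69 ± 1.77 to 13.9 ± 1.70 FPKM.

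Among the falls, model 5834, a protein kinase on chromosome 10 (2517139 to 2520679), went from 13.2 ± 3.23 FPKM in WT to 0.0220, 0 and 0 in the libraries labelled dgk1 (log2 fold change -3.79 ± 0.18, limma adjusted p = 2.73e-05). OS04G0103700, a serine/threonine protein kinase near the start of chromosome 4, fell from 22.2 ± 4.15 to 7.33 ± 1.26 FPKM, and model 9297, with leucine-rich repeats, from 5.89 ± 0.745 to 1.14 ± 0.414. Momilactone A synthase (OS04G0179200), which makes a diterpenoid phytoalexin that rice roots exude, fell from 115 ± 20.3 to 46.6 ± 4.18 FPKM (log2 fold change -1.27 ± 0.21, adjusted p = 0.0427). Cinnamyl alcohol dehydrogenase 8A (OS09G0399800), of a family that makes lignin monomers, fell from 453 ± 63.3 to 243 ± 26.8 FPKM. The transporter-like WAT1-related OS06G0210000 fell from 13.7 ± 1.97 to 6.37 ± 0.615 FPKM. Model 36686, with a CCT motif, fell from 9.99 ± 1.09 to 4.98 ± 1.03, and model 36997, with a legume lectin domain, from 10.2 ± 1.22 to 5.06 ± 0.572.

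Over the fixed lists, 10 of 947 members were called in dgk1 against WT, and 27 of the 36 lists had no called member. The members not yet given, named after their values were seen, were the following. Expansin-like A3 (OS07G0475400), of a family linked to wall loosening, fell from 39.2 ± 2.15 to 24.2 ± 1.74 FPKM, the only called member among 26 expansins. A xyloglucan endotransglucosylase (OS06G0697000), which cuts and rejoins wall xyloglucan, rose from 28.4 ± 6.49 to 64.1 ± 8.14 FPKM, 1 of 14. A peroxidase (OS05G0162000) rose from 59.1 ± 5.76 to 113 ± 20.8, 1 of 73, and a cytokinin-activating phosphoribohydrolase (OS03G0857900) from 92.3 ± 16.7 to 168 ± 16.6 FPKM, 1 of 21. Model 32754, a retrotransposon gag protein on chromosome 7, was listed at 0 in WT and at 33.9, 40.5 and 32.4 FPKM in dgk1. None of 65 auxin, 15 ethylene, 30 jasmonate or 15 aquaporin genes was called by limma, with 4, 2, 2 and 2 at an unadjusted p under 0.05.

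In all, limma called 151 of 22383 models in dgk1 against WT, 119 higher and 32 lower, with 2490 at an unadjusted p under 0.05, and 129 differed by at least 2-fold. Of the 21 genes named for this comparison, 7 kept their call in every alternative that was run for single genes and gave them a value. They were models 25546, 31587, 36605, 5834 and 32754, OS02G0252400 and OS04G0103700. Leaving out any 1 of the 6 libraries ended 10 to 14 of the 21 calls. The count of called models then lay between 80 (without dgk1 replicate 2) and 136 (without WT replicate 1). Over all alternatives run for single genes, the highest limma adjusted p of the 21 was 0.180.

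As whole lists, 4 lay lower in the libraries labelled dgk1 than other genes did. Of 32 histone genes, which package new DNA, 31 lay below WT (median log2 fold change -0.25; 0 called by limma and 9 at an unadjusted p under 0.05; camera adjusted p = 3.33e-06, and adjusted p = 0.814 with an estimated correlation). Without WT replicate 1, whose histone level was the highest, the median was -0.15 (camera adjusted p = 0.0154). Of 22 photosynthesis genes, markers of green tissue, 21 lay below WT (median -0.40; 0 called and 4 at an unadjusted p under 0.05; adjusted p = 0.00225, and 0.814 with an estimated correlation). All 5 fasciclin and arabinogalactan proteins, of the cell surface, lay below WT (median -0.48; adjusted p = 0.00225, and 0.313 with an estimated correlation); none was called over all genes, 3 had an unadjusted p under 0.05 and 2 fell when adjusted over the list alone. Of 5 diterpenoid phytoalexin genes, 4 lay below WT (median -0.75; adjusted p = 0.00893, and 0.408 with an estimated correlation), with 1 called over all genes and 3 when adjusted over the list alone. The mean log2 level of the photosynthesis genes differed within WT, at 2.47, 2.83 and 3.30, and lay at 2.65, 2.57 and 2.23 in dgk1, which sets this list, a sign of green tissue in the root samples, beside the other 3. Its call was lost without WT replicate 3 (adjusted p = 0.251) or dgk1 replicate 3 (0.113), and that of the diterpenoid genes without WT replicate 3 (0.0672) or dgk1 replicate 1 (0.185).

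The libraries labelled OE2 differed from WT at 1557 models, many of them present in 1 of the lines and listed at 0 in the other. OS01G0780900, an antigen-like protein on chromosome 1 (33082114 to 33083394), was listed at 0 in all WT and dgk1 libraries and at 99.0, 83.7 and 92.8 FPKM in OE2 (limma adjusted p = 8.90e-09). Model 7742, with an enoyl-CoA hydratase/isomerase domain, rose from 1.03 ± 0.330 to 79.3 ± 5.16 FPKM (chromosome 10, 22724958 to 22740161, log2 fold change 5.32 ± 0.16, limma adjusted p = 1.595e-07). Model 30907, with an acyl-CoA dehydrogenase domain, fell from 26.5 ± 1.78 FPKM to 0, 0 and 0.0372 (chromosome 6, 13946798 to 13951272, log2 fold change -4.76 ± 0.17, limma adjusted p = 3.99e-07). Metallothionein-like protein 1A (OS11G0704500), of a metal-binding family, fell from 23.1 ± 6.37 to 0.509 ± 0.396 FPKM (chromosome 11, 28827746 to 28828439; log2 fold change -3.99 ± 0.23, adjusted p = 8.83e-06).

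Among the largest changes picked by the rule in OE2 were genes of the NB-ARC type, the class of intracellular immune receptors, and leucine-rich repeat proteins. Neither class was tested as a list. OS12G0204600 lies on chromosome 12, models 10140 and 10043 and OS11G0640300 lie on chromosome 11, and model 39122 lies on chromosome 9. On chromosomes 11 and 12, 18.2% and 13.8% of tested models were called, against 6.96% of all. A local difference thus cannot be told apart from a response of these classes. The purple acid phosphatase, the sulfotransferase and model 8666 given below also lie on chromosome 11. OS12G0204600 rose from 0.105 ± 0.156 to 20.9 ± 5.60 FPKM, and model 10140, a leucine-rich repeat protein, from 0 in WT to 8.55 ± 1.20. OS11G0640300, a leucine-rich repeat protein, was at 9.90 ± 1.70 FPKM in WT, model 39122 at 9.08 ± 2.70 and model 10043 at 6.05 ± 0.286, and all 3 were listed at 0 in the OE2 libraries. Further rises were seen for model 36985, an inhibitor of invertase or pectin methylesterase (0 in WT, 9.64 ± 2.24 FPKM in OE2), ribonuclease 3-like OS06G0358800 (1.34 ± 0.417 to 19.4 ± 1.73), model 23738, an EamA-like transporter (0 in WT, 7.04 ± 1.81), and model 11226, with a C2 domain (0.314 ± 0.0446 to 8.91, 30.8 and 5.52, highest in OE2 replicate 2). The purple acid phosphatase OS11G0549615 fell from 7.18 ± 3.09 to 0.107 ± 0.185 FPKM, the sulfotransferase OS11G0505300 from 22.7 ± 5.88 to 3.12 ± 0.478, and model 8666, with a dimerisation domain, from 6.78 ± 1.18 to 0.00545 ± 0.00943.

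**Figure D2:**
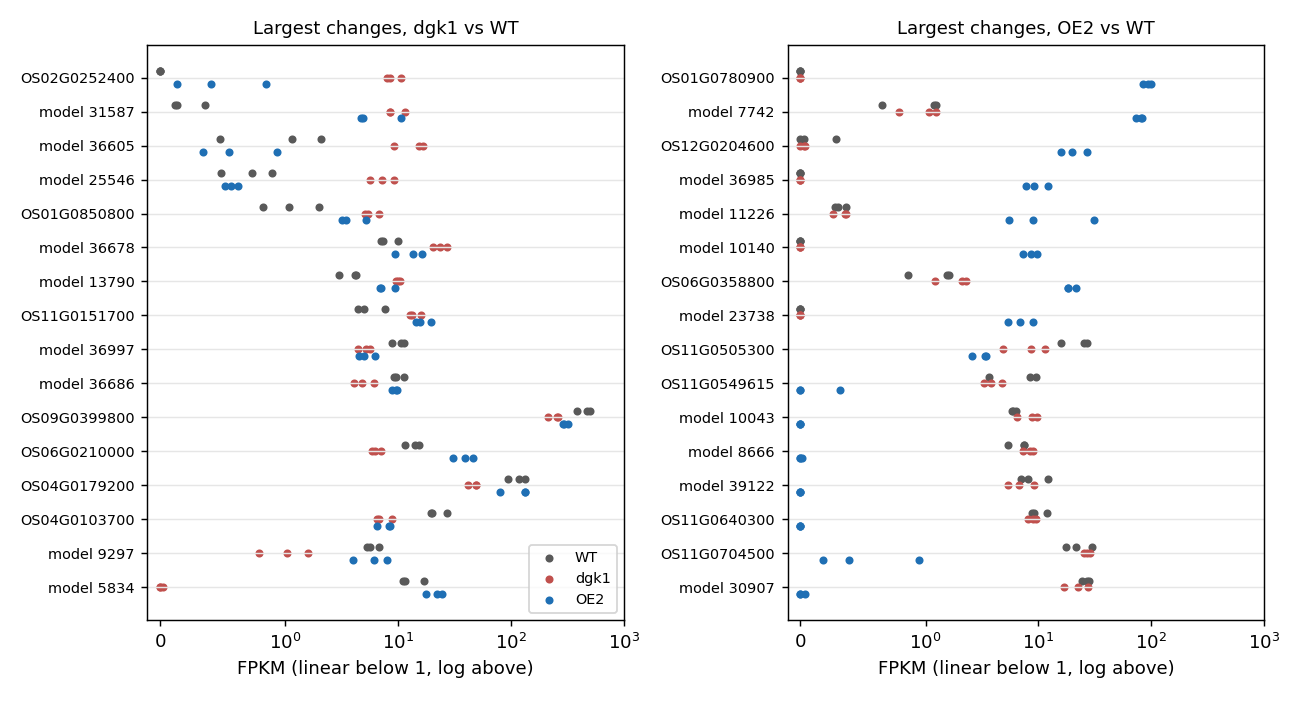
FPKM per library (points, linear below 1 and log above) of the genes with the largest called rises and falls in each line against WT. The ranking covers models with at least 5 FPKM in the higher group, no overlap between replicates and a description that names a function. Some models without such a description changed more. In OE2 against WT, OS01G0780900 lay at 0 FPKM in WT and dgk1 and at 83.7 to 99.0 in OE2; in dgk1 against WT, model 5834 lay at 11.1 to 16.9 FPKM in WT and at most 0.0220 in dgk1.

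In the fixed lists, 60 of 947 members were called in OE2 against WT. Those given here, apart from the histones and ribosomal proteins below, were named after their values were seen. Several carry identifiers of chromosomes 11 and 12, among them alcohol dehydrogenase 2, the laccases and the CASP-like gene below. There 18.2% and 13.8% of tested models were called, against 6.96% of all. For these genes a local difference cannot be told apart from a response of their list. Of 11 hypoxia genes, 3 rose and 1 fell. Alcohol dehydrogenase 2 (OS11G0210500), of fermentation, rose from 592 ± 120 to 1607 ± 498 FPKM (log2 fold change 1.42 ± 0.22, limma adjusted p = 0.00500), non-symbiotic hemoglobin 2 (OS03G0226200) from 69.8 ± 33.7 to 458 ± 171 (2.75 ± 0.40, adjusted p = 0.00353) and hemoglobin 1 (OS03G0233900) from 53.5 ± 22.2 to 159 ± 58.0 FPKM, while model 8527, a zinc-binding dehydrogenase, went from 3.53 ± 1.07 FPKM to 0. In dgk1 these 3 stood at 912 ± 62.9, 163 ± 55.3 and 98.7 ± 18.3 FPKM and none was called. All 3 were highest in OE2 replicate 2, which stood apart on the third component: 2182 FPKM against 1323 and 1316 for alcohol dehydrogenase 2, and 656 against 353 and 364 for hemoglobin 2. Both calls held in every alternative run for single genes, that without this library included (limma adjusted p up to 0.0265 and 0.0158). The call of hemoglobin 1 was lost without 3 of the 6 single libraries (limma adjusted p over all alternatives up to 0.0767). As a list the hypoxia genes were not called (camera adjusted p = 0.403).

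Expansin-like A3 fell to 21.98 ± 2.31 FPKM in OE2 and the xyloglucan endotransglucosylase OS06G0697000 rose to 59.9 ± 6.36, as in dgk1, again the only called members of their lists. As a list, 19 of 26 expansins lay below WT in OE2 (median log2 fold change -0.26, 6 at an unadjusted p under 0.05) and missed the threshold (camera adjusted p = 0.0658). Of 63 lignin and phenylpropanoid enzymes 7 rose and 3 fell, with laccase OS12G0258700 at 5.57 ± 0.276 in WT and 33.8 ± 15.4 FPKM in OE2 and laccase OS12G0257600 at 3.32 ± 0.159 and 0.101 ± 0.132. Of 73 peroxidases 1 rose (OS04G0688500, 40.6 ± 10.5 to 93.3 ± 9.53 FPKM), and of 22 suberin and Casparian strip genes 1 rose (CASP-like OS11G0649400, 3.11 ± 0.305 to 8.53 ± 1.46). No cellulose synthase was called by limma among 16, and 0 had an unadjusted p under 0.05.

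Of 21 genes matched to the cytokinin list 4 fell in OE2 and none rose, the clock-related OS09G0532400 among them. They were OS10G0479500 (15.1 ± 2.94 to 8.09 ± 1.72 FPKM) and OS04G0518800 (11.05 ± 0.671 to 5.95 ± 1.23), both cytokinin-activating phosphoribohydrolases, cytokinin dehydrogenase 3 (OS10G0483500, 8.44 ± 2.20 to 4.39 ± 0.466), which degrades the hormone, and OS09G0532400 (71.3 ± 7.70 to 49.9 ± 3.02), a clock-related response regulator that also made up the whole tested list of circadian genes. Of 65 auxin genes 2 fell, the repressor IAA24 (OS07G0182400, 76.8 ± 8.73 to 48.9 ± 5.46 FPKM) and an auxin efflux carrier (OS06G0232300, 9.59 ± 1.20 to 5.07 ± 0.276). The 4 calls of the cytokinin list and that of IAA24 were each lost without at least 3 of the 6 single libraries. Over all alternatives their limma adjusted p reached up to 0.144. Ethylene receptor 2 (OS04G0169100) rose from 61.0 ± 6.43 to 93.9 ± 2.96 FPKM, 1 of 15 ethylene genes.

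Of 27 pathogenesis-related proteins 3 rose and 2 fell, all chitinases, which cut fungal walls. OS08G0518900 rose from 14.1 ± 3.55 to 53.6 ± 4.79 FPKM and OS11G0702100 from 42.8 ± 13.6 to 113 ± 27.4, while OS11G0701200, on the same stretch of chromosome 11, fell from 59.4 ± 13.2 to 10.2 ± 2.68. Chitinase genes stand side by side there, so fragments shared between copies leave these values uncertain, and the call of OS11G0702100 was lost without 2 of the 6 single libraries (adjusted p up to 0.0567). Of 32 phosphate starvation genes 1 rose (the acid phosphatase OS11G0151700, to 16.6 ± 2.84 FPKM) and 2 fell, and of 15 nitrogen genes 1 rose, the nitrate transport partner OS04G0480200, from 2.01 ± 0.268 to 7.72 ± 1.83 FPKM. A lipin (model 9743) rose from 10.7 ± 0.781 to 18.3 ± 2.25 FPKM, 1 of 16 phospholipases and phosphatases. Lipins are phosphatidate phosphatases, which turn phosphatidic acid back to diacylglycerol. The number of model 9743 lies between those of models 9698 and 10043, both on chromosome 11, where 18.2% of tested models were called. If it lies there too, a local difference cannot be told apart from a response of its list. Of 14 transposon genes 4 rose and 1 fell, with models 39275 and 38748 listed at 0 in WT and dgk1 and at 7.79 to 9.81 and 6.02 to 6.62 FPKM in OE2. All 9 iron acquisition genes lay above WT, but none was called, 3 had an unadjusted p under 0.05, and the list missed the threshold (camera adjusted p = 0.0628).

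Of the 1557 of 22383 models that limma called in OE2 against WT, 831 were higher and 726 lower, 1061 differed by at least 2-fold, and 4618 of all tested models had an unadjusted p under 0.05. Which side held more calls depended on the scaling: 735 were higher and 894 lower after rescaling to total fragments, and 819 and 1048 with voom. Of the 74 called genes of the rule and the lists, 41 kept their call in every alternative that was run for single genes and gave them a value. Leaving out any 1 of the 6 libraries ended 14 (without WT replicate 2) to 23 (without OE2 replicate 3) of the calls. When only the models outside chromosomes 6, 11 and 12 were fitted and adjusted, 740 were called, against 912 of the same models in the test of all models.

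Ribosomal protein genes lay below WT in OE2 for 102 of 120 members, with a median log2 fold change of -0.25 (camera adjusted p = 2.05e-06, and adjusted p = 0.800 with an estimated correlation). The 1 member called was model 9698 on chromosome 11, with ribosomal protein S4 domains. It fell from 4.51 ± 0.593 to 1.35 ± 0.264 FPKM. Histone genes lay below WT for 28 of 32 members (median -0.46; camera adjusted p = 3.18e-05, and adjusted p = 0.800 with an estimated correlation). Over all genes 3 histones fell and over the list alone 10: histone H4 OS01G0835900 from 299 ± 50.5 to 193 ± 11.2 FPKM (log2 fold change -0.62 ± 0.12, limma adjusted p = 0.0193), H2A.7 OS12G0438000 from 195 ± 39.4 to 121 ± 10.7, and H4 OS10G0539500 from 543 ± 57.0 to 375 ± 29.5. Each of these 3 was lost without at least 3 of the 6 single libraries. Over all alternatives their limma adjusted p reached up to 0.101. WT replicate 1, which stood apart on the third component, had the highest mean log2 level of both lists, 6.80 for histones against 6.40 and 6.54 in the other WT libraries, and 6.65 for ribosomal proteins against 6.25 and 6.51. The OE2 libraries lay at 6.18, 6.20 and 6.27 for histones and at 6.33, 6.25 and 6.24 for ribosomal proteins, so WT replicate 2 was not above OE2 in the latter. Both lists kept their call without WT replicate 1 (camera adjusted p = 0.00226 and 0.00791), with medians of -0.31 for histones and -0.16 for ribosomal proteins. The photosynthesis genes lay below WT for 16 of 22 members and were not called (adjusted p = 0.178), nor were the 8 seed storage genes (adjusted p = 0.378).

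**Figure D3:**
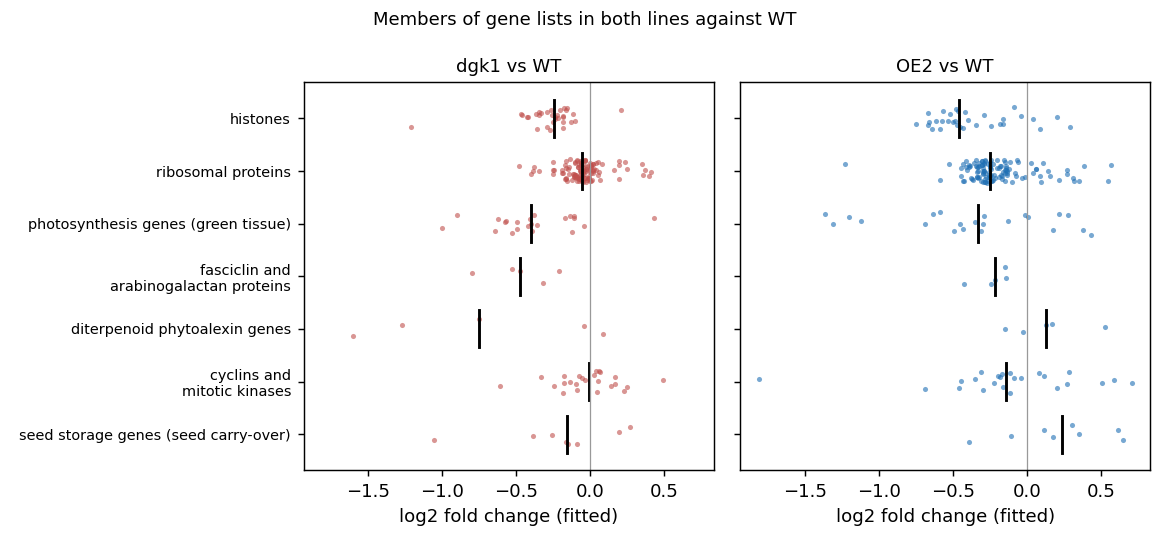
Fitted log2 fold changes of single members (points) and their median (bar) for 7 gene lists in each line against WT. Histones lay below 0 in both panels (31 of 32 members in dgk1, 28 of 32 in OE2), and ribosomal proteins in OE2 for 102 of 120.

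Between the lines, 8 of the genes above stood out in OE2 against dgk1. OS01G0780900, model 7742 and OS12G0204600 lay higher in OE2 as they did against WT, and model 5834, the kinase on chromosome 10, stood at 21.2 ± 3.44 FPKM in OE2 against 0.0220, 0 and 0 in dgk1 (log2 fold change 4.45 ± 0.18, limma adjusted p = 1.11e-06). Model 30907, metallothionein 1A, OS11G0640300 and model 8666 lay lower in OE2, at log2 fold changes of -4.49, -4.24, -3.30 and -3.20. Model 25546, with the span of the targeted gene, was lower in the libraries labelled OE2 (log2 fold change -2.38 ± 0.18, adjusted p = 5.31e-05), the opposite of what the labels of a knockout and an overexpressor give. In all, 1423 models were called, 717 higher and 706 lower in OE2 (622 and 845 after rescaling to total fragments, 713 and 948 with voom). All 9 calls named here held in every alternative run for single genes. Ribosomal proteins lay lower in OE2 for 102 of 120 members (median -0.19, and -0.29 after rescaling to total fragments; camera adjusted p = 0.000667, and adjusted p = 0.932 with an estimated correlation), the only list called.

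Both lines were called against WT at 71 models, 48 higher in both, 16 lower in both and 7 in opposite directions. Among those with a described function, higher in both were the xyloglucan endotransglucosylase OS06G0697000, Laccase-8, the acid phosphatase OS11G0151700 and model 31587. Lower in both were expansin-like A3, cinnamyl alcohol dehydrogenase 8A and the kinase OS04G0103700. In dgk1, expansin-like A3 lost its call without each of the 6 single libraries. Cinnamyl alcohol dehydrogenase 8A, Laccase-8 and OS11G0151700 lost theirs without 5, and OS06G0697000 without 4. Of the 71 models, 8 lay in the first 2 Mb of chromosome 4. Others, such as OS06G0559600, were listed at 0 in all WT libraries and present in both lines. The WAT1-related OS06G0210000 went opposite ways, with 6.37 ± 0.615 FPKM in dgk1 and 38.7 ± 7.58 in OE2 against 13.7 ± 1.97 in WT. Independent lists of these sizes would share 4.42 models higher in both, 1.04 lower in both, 3.86 higher in dgk1 and lower in OE2, and 1.19 the other way. Unchanged groups simulated against the same WT libraries shared 0.02 calls on average and at most 1 in 50 simulations, which is chance with no effect and does not measure what shared controls add to real effects. The log2 fold changes correlated at 0.343 across genes, which are not independent replicates, where the simulated mean was 0.503. Their covariance was 0.101, against 0.0466 simulated. The 3 WT libraries cannot be split into parts of at least 2, so part of the overlap may come from shared controls. Of the 1423 models called between the lines, WT lay between them in 729 (51.2%), which is no sign of a graded order, since a change in 1 line alone puts WT on either side of the other line by chance.

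Called models were gathered in stretches of the genome. Chromosomes 6, 11 and 12 held 645 of the 1557 calls of OE2 against WT (41.4%) with 19.5% of the tested models: 237 of 1829, 237 of 1302 and 171 of 1239. Elsewhere 912 of 18013 models (5.06%) were called. In 31 of 361 windows of 1 Mb with at least 20 tested models, at least 25% were called; they held 496 calls (31.9%) and 5.75% of tested models. The densest window, on chromosome 12 from 8 to 9 Mb, had 74.2% of its models called. The variance of window counts relative to chance was 8.10, with at most 1.28 in 10000 permutations of the calls among models (permutation test, one-sided, p = 0.0001, the smallest these can give), and 4.38 over annotated models alone, with at most 1.38 permuted. It was 1.91 in dgk1 against WT, with at most 1.40 permuted (permutation p = 0.0001), and its densest window, on chromosome 10 from 2 to 3 Mb, had 12.8% called, among them model 5834.

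**Figure D4:**
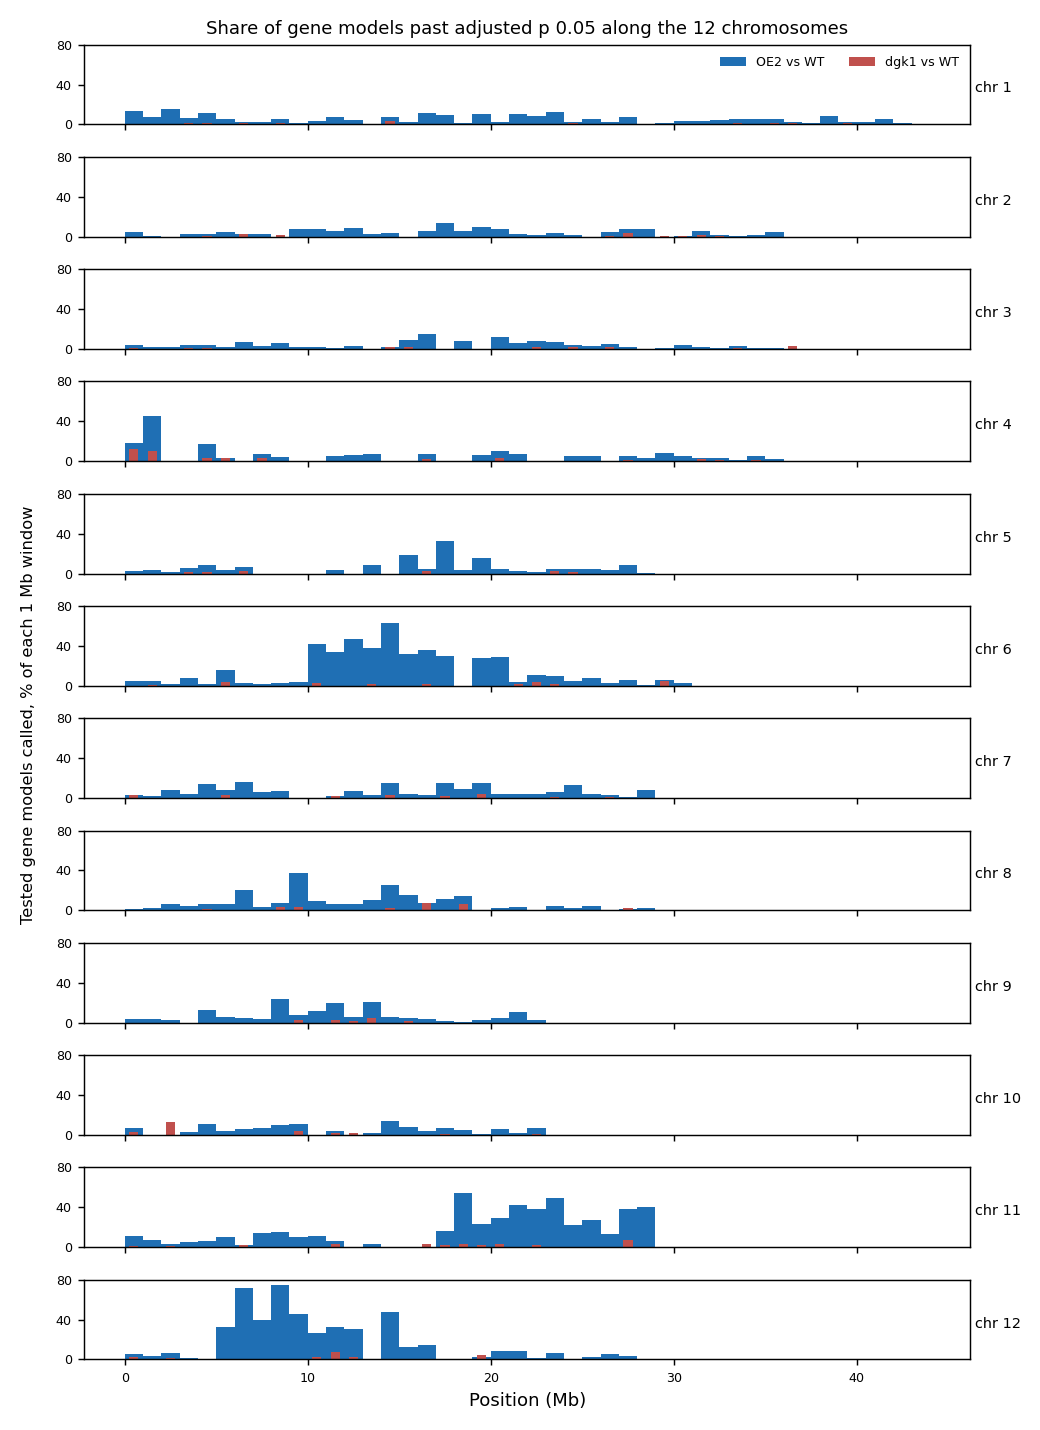
Percentage of tested models called in each 1 Mb window with at least 20 tested models, along the 12 chromosomes, for OE2 against WT (blue) and dgk1 against WT (red). Windows on chromosomes 6, 11 and 12 reach 74.2% in OE2, while no window exceeds 12.8% in dgk1.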

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

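Planned tests that need counts (other count normalizations and a second count test) were not run, because the files hold FPKM. The rescaling, quantile, voom, annotated-only, noncoding-free and chromosome alternatives were chosen after seeing the data. About 47.5% to 51.6% of simulated 2-fold changes were recovered with the same spread for every model, so smaller changes are largely out of reach in that setting. Most false calls in simulation were short noncoding models. Without noncoding models 199, 1699 and 1547 models were called in dgk1 against WT, OE2 against WT and OE2 against dgk1. The cause of the other shifts was not tested, except that stricter filters and subsets test fewer models and leaving out libraries leaves fewer samples. A group with 1 library left out kept 2.

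The 151 calls of dgk1 against WT became 77 with a filter of 5 FPKM, 96 with the 6 libraries alone, 312 with voom, 79 with annotated models only, and 80 to 136 with single libraries left out. The 1557 of OE2 against WT became 794 with that filter, 907 with annotated models only and 740 when only models outside chromosomes 6, 11 and 12 were fitted, and the 1423 of OE2 against dgk1 became 706, 761 and 702. The 729 models with WT between the lines became 386 with that filter and 369 outside those chromosomes. The 64 models moved the same way in both lines became 34 and 40. The 7 moved in opposite ways became 3 under each of these and 3 with no filter. Apart from the replicate block, all other alternatives stayed within 1.5 times these counts.

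Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.161 to 0.0635, with 0 of 9 pairs over 0.1, and 1 of 9 libraries correlated best with its own number. With the replicate number as a block, dgk1 against WT had 73 calls, and the models shared by both lines were 29 in the same and 2 in opposite directions; OE2 had 1156 calls against WT and 1129 against dgk1. The block changed no list's call.

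With an estimated correlation 0 lists were called in each comparison. The 4 lists of dgk1 against WT became 2 outside those chromosomes, where the fasciclin and diterpenoid lists have too few members for a value, and 2 to 6 with single libraries left out. The 2 of OE2 against WT became 4 and 2 to 4. The 1 of OE2 against dgk1 became 2 outside those chromosomes, 2 after rescaling to total fragments and 1 to 2 with single libraries left out.

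Of genes called by name or in a list, 7 of 21, 41 of 74 and 9 of 9 kept their call in all alternatives that were run for single genes and gave them a value. Over 372, 1151 and 192 values for these and the uncalled kinases, 115, 183 and 0 calls were lost and 2, 6 and 0 values, none called, changed sign. With single libraries left out, those ranged from -0.20 to 0.039 (model 34608, dgk1 against WT), -0.11 to 0.061 (model 15899, OE2 against WT) and -0.074 to 0.25 (OS01G0783200, OE2 against WT). Rescaling and quantile normalization moved the median of all genes by less than 0.1 on the log2 scale. Rescaling to total fragments and voom turned the near-even split of OE2 calls toward lower ones: 735 higher and 894 lower against WT with the former and 819 and 1048 with the latter, and 622 and 845, and 713 and 948, against dgk1.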

Other observations

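The tests of segment gain or loss, of another cultivar, of dividing cells in dgk1 alone and all tests at the kinase locus were chosen after the results they measure had been seen; so were the regions and genes named here. The first megabases of chromosome 4 differed in both lines. Of 106 tested models between the start and 2 Mb, 12 were called in dgk1 against WT and 30 in OE2 against WT, 8 of them in both and 7 of these in the same direction. OS04G0103800 lay at 28.5, 36.0 and 34.6 FPKM in WT, was listed at 0 in all dgk1 libraries and lay at 0.111, 0.117 and 0 in OE2. Also near the start, OS04G0103601 lay at 1.96, 1.82 and 1.53 FPKM in WT, 30.7, 36.7 and 43.1 in dgk1 and 27.7, 34.2 and 24.2 in OE2. OS04G0115700 was listed at 0 in WT and lay at 123, 163 and 63.8 FPKM in dgk1 and 3.77, 1.34 and 4.23 in OE2. OS04G0121800 lay at 179 to 190 FPKM in WT and 214 to 240 in dgk1, and was listed at 0 in OE2.

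Of 33 glutathione S-transferases, which detoxify by conjugation, 3 rose and none fell in OE2 against WT (limma), among them OS10G0530200 from 10.95 ± 1.71 to 24.98 ± 2.95 FPKM (SD, n = 3). The other 2, OS10G0529500 and model 11044, lost their call without 4 and 3 of the 6 single libraries. Over all alternatives their limma adjusted p reached up to 0.126 and 0.0865. The number of model 11044 lies between those of models 10263 and 11163, both on chromosome 12, where 13.8% of tested models were called. A local difference cannot be told apart if it lies there too. Of 81 heat shock proteins 1 rose (OS03G0266900, 12.03 ± 0.968 to 23.9 ± 2.78 FPKM) and 1 fell (OS07G0517100, 41.6 ± 7.79 to 12.8 ± 3.57). Of 34 NAC factors 1 rose (OS05G0442700, 5.29 ± 0.929 to 15.7 ± 1.63 FPKM) and 1 fell, and of 24 cyclins and mitotic kinases 1 rose and 1 fell. Among these, cyclin-dependent kinase F-1 (OS06G0334400), rose from 41.6 ± 3.67 to 68.7 ± 5.42 FPKM. The calls of OS03G0266900 and OS06G0334400 were each lost in 1 alternative. Levels of the 9 iron acquisition genes were uneven within OE2, with a mean log2 level of 5.24 in replicate 2 against 4.01 and 3.87 in the others.

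The calls of OE2 against WT gathered in 27 windows of chromosomes 6, 11 and 12. Gain or loss of all the windows of a chromosome together was argued against on chromosomes 11 and 12. There the median log2 fold change of all tested models in the windows was 0.04 (95% bootstrap interval -0.02 to 0.16) and 0.20 (0.08 to 0.27). Of the called models, 92 were higher and 60 lower on chromosome 11, and 94 and 33 on chromosome 12. On chromosome 6 the median was -0.32 (-0.45 to -0.23), with 39 called models higher and 120 lower. A median over all windows of a chromosome cannot exclude gain or loss of single segments. Gain of part of the chromosome 12 segments and loss of part of the chromosome 6 segments thus cannot be told apart. A cultivar that differs from WT in most windows was argued against too, since the median window had 4.88% of its models called and 38 of 361 windows had 0. A related cultivar that differs only in some stretches cannot be told apart, since it too would leave most windows with few calls. As a hypothesis, the windows may be background segments of another haplotype in the line: of called models inside them, 82 of 438 (18.7%) were at 5 FPKM or more in all libraries of 1 group and at 0.2 or less in all of the other, against 73 of 1119 (6.52%) outside (Fisher's exact test, odds ratio 3.30, 95% interval 2.32 to 4.69, p = 6.99e-12). The windows were picked on these same calls, so the test is no independent support for the hypothesis. In all 31 windows passed the 25% cut, and those on other chromosomes were counted as outside. Genes are not independent within a segment, no sequence was examined, and an effect of the kinase on these genes stays open as untested.

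At the kinase locus, model 25546 was higher in the libraries labelled dgk1 and not in those labelled OE2. An exchange of the labels of both lines cannot be told apart at this depth, since the OE2 to WT ratio of 0.848 has an interval that includes 1. Fragments shared by overlapping models could be missing from the values, as 76.0% of annotated models with a numbered partner of the same span were listed at 0, but how many fell here is not in the files, so this stays open and could hide an overexpressed transcript. A local change, for example around an insertion, may raise neighbours as well. The largest value among tested neighbours within 20 kb was 0.81 on the log2 scale (OS04G0634400, limma adjusted p = 0.106), and model 25549 lay at 0.36 ± 0.42. The untested model 25544 had 19, 8 and 22 fragments in WT and 52, 39 and 85 in dgk1. The best-expressed neighbour, OS04G0634800, lay at -0.25, OS04G0634900 at -0.13 and OS04G0635000 near 0. With 3 of 5 tested neighbours under 5 FPKM, a local change cannot be told apart. The labels' own reading, a knockout and an overexpressor, needs values from within the transcript, which were not analysed here.

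Histone genes lay lower in both lines than in WT. A single WT library was argued against as the whole source, since with each left out in turn the list kept its call in both lines (highest adjusted p = 0.0154, without WT replicate 1 in dgk1, at the preset correlation), but part of the shift came from WT replicate 1, without which the medians were -0.15 in dgk1 and -0.31 in OE2. Fewer dividing cells may lower both histones and replication genes. The median of 63 genes matched on descriptions of replication and mitosis was -0.04 in dgk1 and -0.20 in OE2, against histone medians of -0.25 and -0.46. Many of the 63 were matched on the word kinesin, kinesin light chain-like proteins among them, so the list is not specific to dividing cells. The replication median lay above 0.5 of the histone median by 0.928 standard errors of the replication median in OE2 (0.734 of the gap). There 52 of the 63 genes lay below 0 (camera unadjusted p = 0.000248, and 0.248 with an estimated correlation). In dgk1, where 38 of the 63 genes lay below 0, the distance was 2.66 standard errors of the gap with all libraries. Without dgk1 replicate 3 it was 1.57. With such a list, fewer dividing cells cannot be told apart in either line. With an estimated correlation neither list was called, so the pattern itself stays a hypothesis.

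Chance in the grouping was examined by splitting the 6 libraries of each comparison in all 10 ways. In each comparison 1 of the 10 splits, the real one, gave as many calls: 151 in dgk1 against WT with at most 2 in the other splits, 1557 in OE2 against WT with at most 3, and 1423 in OE2 against dgk1 with at most 2. The 10 splits are too few for a share under 0.05.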
